A study of Rattus norvegicus with 12 samples.

How the data were processed

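Kidney RNA from 12 male Zucker rats was measured on Affymetrix Rat Genome 230 2.0 arrays, 1 array per rat, with 3 rats in each of 4 groups. Per the labels, total RNA was extracted with Trizol and labelled with biotin using an Enzo transcript labelling kit. The deposited values are signal intensity values on a linear scale, made by the authors with MAS5, which the submitters' processing notes name without a version. The scanner settings, the scaling target and any later step are not given in the sources used here. The deposited values themselves showed how the arrays had been scaled: after trimming 2% of the probe sets at each end, the 12 array means lay between 500.12 and 500.15. The table was therefore used as deposited, with no further normalization. The number of arrays limits the precision of every value below.

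The table held 31099 probe sets. The 57 Affymetrix control probe sets were left out, and 31042 remained. Of these, 20826 carried 1 gene symbol, 436 carried several and 9780 were unnamed here. The gene IDs of 20764 probe sets were found in the gene table of the GRCr8 assembly and 0 symbols had to be updated. Signals were turned to log2 after adding an offset of 16. Probe sets whose mean log2 value over the 12 arrays lay below the 40th percentile, 7.32, were left out, which kept 18625 probe sets.

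All 12 arrays entered 1 linear model with 4 group means (limma 3.58.1 with statmod 1.5.0 in R 4.3.3), which left 8 residual degrees of freedom. Spreads were moderated with limma's eBayes with trend and robust settings, and p-values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons. A probe set was called at an adjusted p under 0.05. The comparisons were obese against lean on control diet, on rosiglitazone and over both diets, rosiglitazone against control in lean rats, in obese rats and over both body types, and the difference in the rosiglitazone effect between body types. Fold changes are given on the log2 scale with their standard error (SE), and group values as mean signal ± SD. A gene is called non-overlapping when every array of one group lay above every array of the other, within each diet or body type where both were combined.

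Fixed gene lists, 29 in number, were tested with camera from limma at its preset correlation between genes of 0.01, with 1 probe set per gene (that of the highest mean), a background of 10524 genes, at least 5 measured genes per list, and adjustment over the lists. The same lists were tested with camera at an estimated correlation and with fry from limma. The lists covered fatty acid oxidation and PPARalpha targets, PPARgamma targets, adipocyte markers, fatty acid synthesis, cholesterol synthesis, sodium and water transport of the distal nephron, markers of the thick ascending limb and medulla, intercalated cells, proximal tubule, podocytes, endothelium and smooth muscle, the renin angiotensin system, tubular injury, fibrosis and extracellular matrix, inflammation and leukocytes, lymphocyte markers, glucose metabolism and insulin signalling, oxidative stress and glutathione, oxidative phosphorylation, eicosanoid metabolism, xenobiotic metabolism and transporters, the circadian clock, immediate early and heat shock genes, red blood cell genes, adrenal cortex markers, urothelium markers, cell cycle, and the unfolded protein response. The red blood cell and adrenal cortex lists had fewer than 5 measured genes and were not tested as lists, so 27 were.

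The genes named in the text followed a rule. In each comparison, up to 8 genes with the highest and up to 8 with the lowest log2 change were taken among called, non-overlapping probe sets with 1 symbol, leaving out predicted genes. Where a gene had several such probe sets, that of the highest mean was named, whatever its rank. Where fewer than 5 probe sets passed, the 10 of smallest p were named and are said not to pass. From each list past camera, or with at least 3 called members, up to 4 members of smallest p could be named. A set of genes of interest for this tissue and drug was always looked up, from Lepr and Pparg to Havcr1 and Slc5a2, as were Adipoq, Hbb, Alas2, Fos, Dbp, Per2 and Cd74 as checks on the make-up of the samples. Ppara and Lcn2 lay below the filter on dim probe sets, and some other genes of the set are not reported here. The model, filter, threshold, gene lists, naming rule and most of the alternatives below were chosen before the data were examined.

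The relation between the body type difference and the rosiglitazone effect was described by correlations across probe sets, set beside 100 simulations of unchanged groups that share the same arrays. The procedure was tested on simulated data of the same size, in which 50 probe sets were changed at each fold. On the control diet, 38% of changes of 1.5-fold, 80% of 2-fold, 92% of 3-fold and 94% of 4-fold were recovered, with 6 false calls. In the comparison over both diets, the shares were 74%, 90%, 98% and 100%, with 6 false calls. A simulated comparison with no change gave 0 calls.

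The alternatives chosen beforehand were no offset and an offset of 64, no filter and a filter at the 60th percentile, quantile normalization, centring each array on its median, eBayes without trend and robust, a fit of the compared groups alone, array quality weights, the replicate number of the labels as a block, a threshold of 0.1, and leaving out each array in turn. Lists were also tested with the mean over a gene's probe sets. The signal of the cre hybridization spike-in parted the arrays into a higher class of 5 and a lower class of 7. This class was found after the array summaries were seen, and the alternatives that use it were added then. Within a class some groups hold 1 array, so the spread comes from the groups of that class with more, and the lone array is assumed to vary like them. Tables and simulations were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No array was left out and 0 columns of the table were left unmapped. Bacterial control probe sets, read as a measure of background after the values were seen, gave up to 70.5. The outlier test was not applied, since groups of 3 are too small for it.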

Results

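Kidney gene expression was measured in 12 Zucker rats, all male, of which 6 were lean and 6 obese. Obese Zucker rats carry a mutated leptin receptor, and the labels describe the animals as a model for diabetes. Within each body type, 3 rats ate ground chow (control diet) and 3 ate the same chow with rosiglitazone at 3 mg/kg body weight for 12 weeks. Rosiglitazone is an agonist of PPARgamma, a nuclear receptor that controls fat cell genes, and the series title gives its effect on kidney expression as the subject. The median signal per array lay between 204.01 and 238.62. In a principal component analysis, component 1 held 29.6% of the variance and parted lean from obese rats, with scores from −26 to −11.48 in lean and from 16.9 to 25.95 in obese rats, and component 2 held 13.6%. On component 2 lean rosiglitazone 3 had −35.64 and the other arrays −13.39 to 17.8, and its median correlation with its own group was 0.953, against 0.96 to 0.977 for the others. The ratio of 3' to 5' signal of Gapdh, a measure of RNA integrity, ranged from 1.07 to 1.32, that of actin from 1.57 to 2.40 and that of hexokinase from 1.80 to 2.95. The signal of the cre spike-in, a control added at hybridization, was 19916 to 21951 in a higher class of 5 arrays and 14412 to 16658 in a lower class of 7. Arrays 1 and 2 of both lean groups and array 1 of the obese control group were in the higher class, and all 3 arrays of the obese rosiglitazone group were in the lower class. Bacterial control probe sets, 3 in number, gave 0.848 to 70.5. A group mean under 70.5 is called at background here, and a log2 change from it depends on the offset and is not exact.

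Obese and lean kidneys were first compared on control diet. Ucp1, the uncoupling protein of brown fat, had a signal of 776 ± 133 in lean and 14.6 ± 15.8 in obese rats (SD, n = 3 each; log2 change −4.80, SE 0.46, adjusted p = 0.000108). The obese signal was at background, and the log2 change ran from −6.30 with no offset to −3.42 with an offset of 64. Slc22a13, a renal organic anion transporter, had 728 ± 145 in lean and 80.5 ± 26.9 in obese rats (log2 change −2.97, SE 0.24, adjusted p = 9e-06). Ace, angiotensin converting enzyme, had 605 ± 39 and 233 ± 15.7 (log2 change −1.32, SE 0.13, adjusted p = 5.9e-05). Among the genes higher in obese kidneys, Ccn1, a matrix protein gene, had 104 ± 16.6 in lean and 491 ± 169 in obese rats (log2 change 2.03, SE 0.23, adjusted p = 0.000233). Spp1, which encodes osteopontin, had 6942 ± 1237 and 13705 ± 4009 (log2 change 0.95, SE 0.19, adjusted p = 0.0148).

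In all, 882 probe sets of 645 genes differed on control diet, 401 higher and 481 lower in obese rats, and 160 of them by at least 2-fold. Unadjusted p was under 0.05 for 3517 of the 18625 probe sets. Of the 882, 881 were non-overlapping between the groups. Over all probe sets, 25.5% were non-overlapping, where chance gives 10%. Higher probe sets made up 45.5% of the calls, but 32% (242 of 756) with each array centred on its median, so the balance of directions rests on the scaling. The other higher genes named by the rule were RT1-Bb at 2.87 and Ubd at 2.31, both of immune function, the RNA methylation factor gene Wtap at 2.68, Apcs at 1.99, Lypd2 at 1.97, Sfrp2, an inhibitor of Wnt signals, at 1.74, and Rab8b at 1.70. The other lower ones were Cox8b, a respiratory chain subunit of muscle and brown fat, at −2.98 (obese signal at background, −2.14 with offset 64), RT1-CE16 at −2.95, Thrsp, a regulator of fat synthesis, at −2.65, Gtpbp4 at −2.28, Pamr1 at −1.93 and AKR1C3l1 at −1.90. A second probe set of Wtap gave 0.48 (adjusted p = 0.0586) and a second one of Rab8b gave 0.15 (adjusted p = 0.702), so neither gene's probe sets gave 1 answer. The rule takes the probe set of highest mean, and dimmer ones, chosen after their values were seen, lay further out. RT1-Db1 had 3.64 (adjusted p = 2.42e-06, from 54.4 ± 31.2, at background, to 818 ± 149; 2.91 with offset 64), with its brighter probe set at 1.09, Fubp3 2.41, with its brighter one at −0.47, Nt5dc1 2.20 and Cav2 2.02. Gtpbp4 had −3.11 (adjusted p = 2.42e-06), Thrsp −2.88 and Pxmp4 −2.46.

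Of the 27 fixed lists tested, 12 passed camera on control diet. The adipocyte markers had 0 of 14 measured members that rose and 5 that fell (0 and 6 adjusted over the list alone), with a median log2 change of −0.53 (adjusted p = 1.73e-07, and adjusted p = 0.139 with an estimated correlation). Next to Ucp1 and Thrsp these included Cfd, the adipsin gene, at −1.87 (SE 0.32, adjusted p = 0.00508) and Fabp4, the fatty acid binding protein of fat cells, which went from 1514 ± 774 to 403 ± 162 (log2 change −1.85, SE 0.37, adjusted p = 0.0142). Adipoq, the fat cell hormone adiponectin, had 635 ± 41.8 and 500.4 ± 125 (log2 change −0.36, adjusted p = 0.306) and did not pass. Of the fatty acid synthesis genes, 0 of 19 rose and 5 fell (0 and 13 adjusted over the list alone; median −0.44, adjusted p = 1.81e-07, and adjusted p = 0.139 with an estimated correlation). Fasn, fatty acid synthase, fell by 1.69 on the log2 scale (SE 0.27, adjusted p = 0.00406), Pnpla3 by 0.90 and Me1 by 0.50. Other probe sets of Pnpla3 (−0.64 and −0.15) did not pass. Scd, the stearoyl-CoA desaturase, had 1865 ± 2001 in lean and 139 ± 25.6 in obese rats, did not pass (adjusted p = 0.122), and had lean control signals of 1383, 149.5 and 4063.5. Of the PPARgamma targets, 2 of 29 rose and 5 fell (4 and 7 adjusted over the list alone; median −0.21, adjusted p = 0.00521, and adjusted p = 0.415 with an estimated correlation). Within it Aqp7 fell by 0.61 and Lpl, lipoprotein lipase, rose by 0.76 (adjusted p = 0.0356). The PPARgamma and fatty acid synthesis lists share members with the adipocyte markers. The labels do not say how the fat around the kidneys was removed, so the changes of these lists are not shown to lie in kidney cells.

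Transport genes moved in both directions on control diet. Sodium and water transport of the distal nephron had 5 of 24 members that rose and 0 that fell (14 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.000172, and adjusted p = 0.0649 with an estimated correlation). Scnn1b, a subunit of the epithelial sodium channel, rose by 0.63 (SE 0.14, adjusted p = 0.0178), the kinase gene Wnk1 by 0.62 (SE 0.12, adjusted p = 0.011), and Nr3c2, the mineralocorticoid receptor, by 0.55 (adjusted p = 0.0127). Another probe set of Wnk1 gave −0.02 (adjusted p = 0.968). Aqp2, the water channel of the collecting duct, had a change of −0.02 (adjusted p = 0.946) and Scnn1g one of 0.45 (adjusted p = 0.241). The proximal tubule markers had 1 of 29 members that rose and 9 that fell (3 and 13 adjusted over the list alone; adjusted p = 6e-04, and adjusted p = 0.415 with an estimated correlation). Their median was −0.29 and their mean 0.02, so the mean differed in sign from the median and the test, and the median was −0.14 after quantile normalization and −0.12 within the lower spike-in class. The organic anion transporter gene Slc22a7 went from 1308 ± 185 to 465 ± 50.2 (log2 change −1.46, SE 0.14, adjusted p = 5.87e-05), Slc13a3 from 6305 ± 549.7 to 3006 ± 308 (−1.07, adjusted p = 3e-04), and Anpep fell by 0.69. Slc5a2, the glucose transporter SGLT2, had a change of 3.23 (SE 1.05, adjusted p = 0.116). Its signals in lean control arrays 1 and 2 were at background, and that in array 3, of the lower spike-in class, was higher, so this change is not exact. The renin angiotensin list had 0 of 9 members that rose and 2 that fell, Ace and Anpep (1 and 2 adjusted over the list alone; median −0.27, adjusted p = 0.012, and adjusted p = 0.415 with an estimated correlation), and its median was −0.04 within the lower spike-in class.

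Lists of injury and matrix were higher on control diet. Fibrosis and extracellular matrix had 2 of 25 members that rose, Ccn1 and Col4a1, and 0 that fell (4 and 0 adjusted over the list alone; median 0.38, and 0.18 within the higher spike-in class; adjusted p = 0.00201, and adjusted p = 0.452 with an estimated correlation). Tubular injury had 3 of 22 that rose and 2 that fell (7 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.0112, and adjusted p = 0.415 with an estimated correlation). Spp1, Cd44 and Anxa1 rose (other probe sets of Cd44 and Col4a1, at 1.03 and 0.39, did not pass), while Krt19, a keratin, fell by 1.56 (SE 0.23, adjusted p = 0.00204) and Tff3, a secreted trefoil peptide, fell by 0.64. Havcr1, which encodes the injury marker KIM-1, had 152 ± 58.8 in lean and 1183 ± 1237 in obese rats (log2 change 2.33, SE 0.70, adjusted p = 0.0831), with obese control signals of 2592, 277 and 679. Smooth muscle markers had 0 of 9 members past the test over all genes (4 higher and 1 lower adjusted over the list alone; median 0.38, and 0.02 within the higher spike-in class; adjusted p = 0.0184, and adjusted p = 0.415 with an estimated correlation). Inflammation and leukocytes had 2 of 27 that rose, RT1-Bb and RT1-Ba, and 0 that fell (5 and 0 adjusted over the list alone; median 0.23, 0.12 with the spike-in class as a covariate and 0.09 within the lower class; adjusted p = 0.0176, and adjusted p = 0.551 with an estimated correlation). RT1-Ba had another probe set at −2.65 (adjusted p = 0.0325). Cd74, the invariant chain of class II molecules, had −0.21 (adjusted p = 0.295). The unfolded protein response had 0 of 21 that rose and 1 that fell, Creld2 (0 and 3 adjusted over the list alone; median −0.22, adjusted p = 0.012, and adjusted p = 0.551 with an estimated correlation). Oxidative phosphorylation had 0 of 44 that rose and 1 that fell, Atp5f1d (0 and 0 adjusted over the list alone; median −0.10, adjusted p = 0.00322, and adjusted p = 0.637 with an estimated correlation). Its median was 0.02 after quantile normalization, so its direction turned with the scaling.

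The other 15 lists did not pass on control diet. Their adjusted p was 0.056 for cell cycle, 0.0835 for cholesterol synthesis, 0.0855 for podocytes and for xenobiotic metabolism, 0.109 for oxidative stress, 0.119 for immediate early genes, 0.157 for fatty acid oxidation, 0.181 for intercalated cells, 0.72 for glucose metabolism and for eicosanoids, 0.874 for lymphocytes and for urothelium, 0.949 for the thick ascending limb, 0.986 for the circadian clock and 0.992 for endothelium. Lepr, the mutated receptor gene, had 141 ± 49.9 and 157 ± 38.6 (log2 change 0.18, adjusted p = 0.778), and Pparg, the drug's receptor, had 189 ± 29.9 and 203 ± 47.7 (log2 change 0.08, adjusted p = 0.896). The spike-in class moved with body type, since 2 of 3 lean control arrays and 1 of 3 obese control arrays were in the higher class. Within the lower class (1 lean against 2 obese) 164 probe sets were called and within the higher class (2 against 1) 52, where the lone array is assumed to vary like the other groups of its class. With the class as a covariate the count was 995, of which 793 were among the 882. Without 1 array the count ranged from 325 to 1003: 325 without obese control 2, 331 without obese control 3, 385 without lean control 1, 545 without lean control 2 and 546 without obese control 1.

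Several named genes did not pass on control diet without single arrays. These were Fabp4 without obese control 1 (adjusted p = 0.055), Spp1 without lean control 1 (0.0638) or obese control 3 (0.0509), Ubd without lean control 1 (0.0695), lean control 2 (0.0576) or obese control 1 (0.0653), Wnk1 without lean control 1 (0.0558) or obese control 2 (0.0617), and Nr3c2 without obese control 2 (0.071) or obese control 3 (0.0644). Scnn1b, whose adjusted p ranged from 0.00805 to 0.0759 over the alternatives, did not pass without any 1 of the obese control arrays. Me1 (adjusted p up to 0.0991 over the alternatives), RT1-Ba (up to 0.0903), Rab8b (up to 0.0788), Lpl (up to 0.141), Lypd2 (up to 0.139), Cd44 (up to 0.158), Col4a1 (up to 0.17), Creld2 (up to 0.167) and Atp5f1d (up to 0.297) did not pass without at least 3 of the arrays in turn. Lypd2, Cd44 and Atp5f1d did not pass after quantile normalization either, nor Lpl, Lypd2, Cd44 and Col4a1 after median centring.

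**Figure D1:**
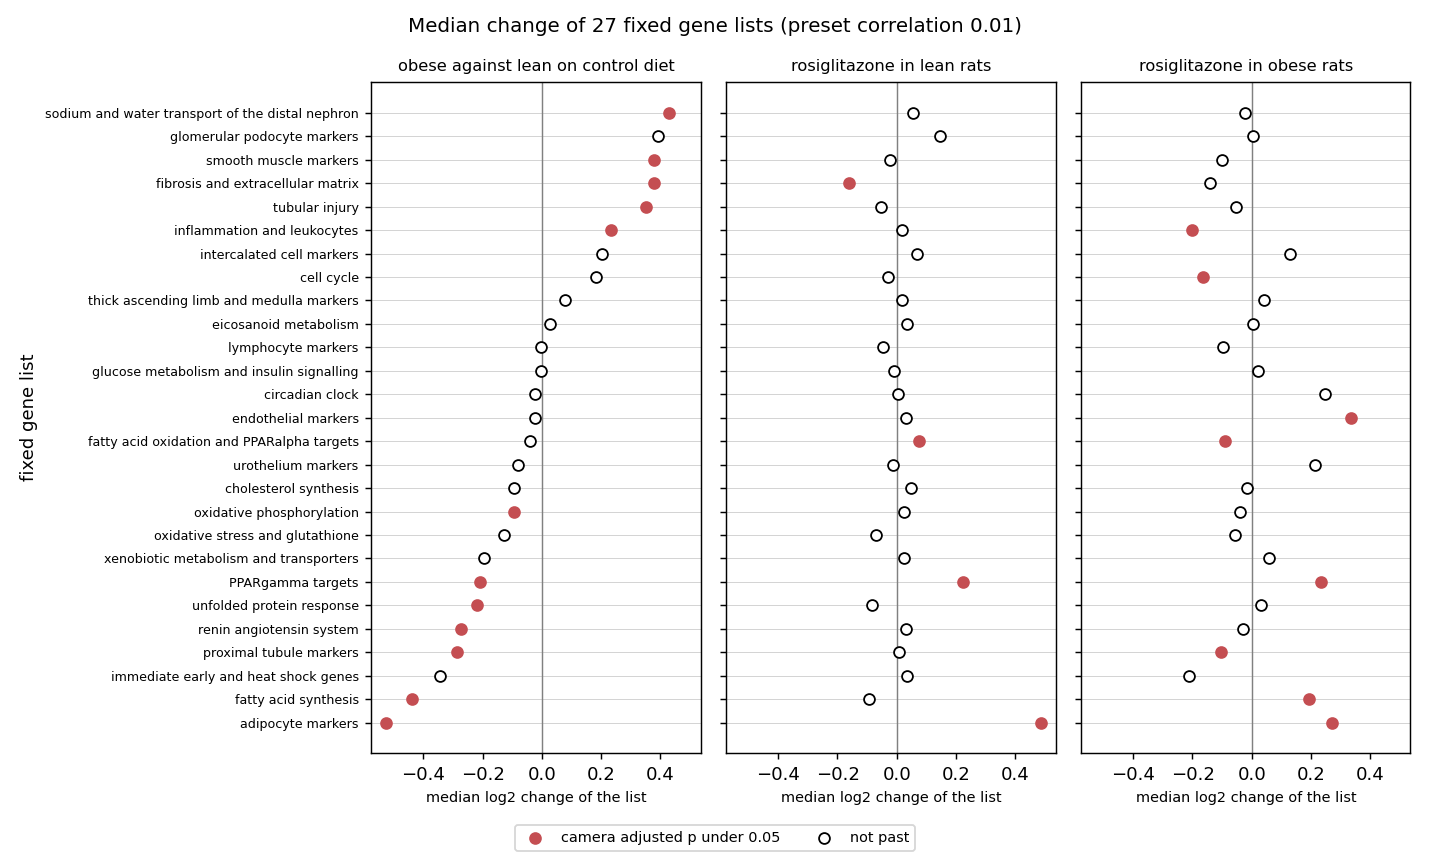
Median log2 change of the measured genes of 27 fixed lists (x axis) for obese against lean on control diet, rosiglitazone in lean rats and rosiglitazone in obese rats (n = 3 per group), where filled points mark lists with a camera adjusted p under 0.05. Adipocyte markers sat at −0.53, 0.49 and 0.27 in the 3 comparisons, and the median of oxidative phosphorylation on control diet turned sign after quantile normalization.

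The comparison of rosiglitazone with control diet in lean rats asks what the drug did in kidneys without obesity. Inmt, which encodes indolethylamine N-methyltransferase, rose from 2024 ± 329.8 to 5300.5 ± 107 (SD, n = 3 each; 2.63-fold, log2 change 1.39, SE 0.11, adjusted p = 6.5e-05). It was the 1 probe set that passed, and its groups were non-overlapping. In obese rats Inmt had 5996 ± 587 on control diet and 7123 ± 418 on the drug. Car3 and Cd36 had higher means on the drug but did not pass. Car3, carbonic anhydrase 3 of fat and muscle, had 833 ± 384 on control diet and 3618 ± 1200.4 on the drug (log2 change 2.14, SE 0.32, adjusted p = 0.0635), and Cd36, a fatty acid uptake receptor, had 367 ± 105 and 928 ± 182 (log2 change 1.32, SE 0.21, adjusted p = 0.0635).

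Of the 10 probe sets of smallest p, those other than that of Inmt did not pass. Among them Rbp7, a retinol binding protein gene, had 103 ± 14.6 and 441 ± 129 (log2 change 1.90, adjusted p = 0.0845), Ces1d, a carboxylesterase gene, 1.05 (adjusted p = 0.0845), Nrxn2 −1.68 (from 226.8 to 62.7, at background) and Fxr2 −0.88 (adjusted p = 0.0635 each), and an unnamed probe set −0.82 (adjusted p = 0.0615). Unadjusted p was under 0.05 for 893 probe sets, and 10 passed at an adjusted p of 0.1. The 893 are fewer than the share of 0.05 of the 18625 probe sets that chance alone gives. Over all probe sets 8.5% were non-overlapping, where chance gives 10%. The adjusted p of Inmt ranged from 1.24e-05 to 0.00549 over the alternatives. Without lean control 2 the count was 4, and without lean rosiglitazone 3, apart on component 2, it was 2. Each group had 2 arrays in the higher spike-in class and 1 in the lower, and the count was 0 within the higher class (limma, 713 at an unadjusted p under 0.05) and 23 within the lower. There 1 array stood against 1, so the spread came from the obese groups alone and the 23 say little about the class.

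In lean rats 4 lists passed camera, with no member past the test over all genes. All 14 adipocyte markers had higher means on the drug (6 higher and 0 lower adjusted over the list alone; median 0.49, adjusted p = 4.76e-11, and adjusted p = 0.132 with an estimated correlation). The fat cell signals varied widely between rats on the drug. Ucp1 had 3109 ± 2056 against 776 ± 133 on control diet, Cidea, a lipid droplet protein gene, 1902 ± 1012 against 635 ± 157 (log2 change 1.47, adjusted p = 0.264), Fabp4 5154 ± 1836 against 1514 ± 774 (1.81, adjusted p = 0.293) and Adipoq 948 ± 210.0 against 635 ± 41.8 (0.54, adjusted p = 0.981). The adipocyte median was 0.16 within the lower spike-in class and 0.88 within the higher. The PPARgamma targets, which share Ucp1, Cidea, Fabp4 and Adipoq with the adipocyte markers, had 8 higher and 0 lower of 29 adjusted over the list alone (median 0.22, and 0.08 within the lower spike-in class; adjusted p = 5.1e-09, and adjusted p = 0.132 with an estimated correlation). Pparg had a change of 0.35, Lpl one of 0.39 and Angptl4 one of 0.75, and none of these 3 passed. Fatty acid oxidation was higher (1 and 0 of 28 adjusted over the list alone; median 0.07, adjusted p = 0.0237, and adjusted p = 0.998 with an estimated correlation), with Cpt1b at 0.68 and Acadl at 0.26. Fibrosis and extracellular matrix was lower (0 and 0 of 25 adjusted over the list alone; median −0.16, adjusted p = 0.00964, and adjusted p = 0.998 with an estimated correlation), with Timp1 at −0.97, Col1a1 at −0.61 and Ccn2 at −0.44.

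The comparison of rosiglitazone with control diet in obese rats asks what the drug did in the kidneys of obese animals. Among the genes called, Fabp4 had the highest log2 change and rose from 403 ± 162 to 3249.7 ± 747 (SD, n = 3 each; 8.16-fold, log2 change 3.03, SE 0.37, adjusted p = 0.0185). Rbp7 rose from 42.8 ± 25.2 to 252 ± 70.9 (log2 change 2.26, SE 0.33, adjusted p = 0.022), where the control signal was at background and the change was 1.57 with offset 64. Fasn rose from 698 ± 125 to 2233 ± 298 (1.66, SE 0.27, adjusted p = 0.0486). Fabp5, another fatty acid binding protein gene, rose from 2470.1 ± 235 to 4384 ± 643 (0.82, SE 0.11, adjusted p = 0.0217). The renal transporter gene Slc22a13 rose from 80.5 ± 26.9 to 383 ± 67.2 (2.07, SE 0.24, adjusted p = 0.00889). Spns2, a sphingosine 1-phosphate exporter gene, fell from 1169 ± 98.4 to 607 ± 44.1 (−0.93, SE 0.13, adjusted p = 0.022).

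In all 13 probe sets of 11 genes passed in obese rats, 9 higher and 4 lower. The others were Nkd2, an inhibitor of Wnt signals, at 1.57 (adjusted p = 0.0263), Tro at 1.02 (adjusted p = 0.022), the amino acid transporter gene Slc7a12 at 0.82 (adjusted p = 0.022), Cotl1, an actin binding protein gene, at −0.76 (adjusted p = 0.0313), and 2 unnamed probe sets. Ace, which was chosen after its values were seen, rose by 0.77 (SE 0.13, adjusted p = 0.0486), from 233 ± 15.7 to 407 ± 41.2. All 13 were non-overlapping, and over all probe sets 11.9% were, where chance gives 10%. Unadjusted p was under 0.05 for 917 probe sets, and 26 passed at an adjusted p of 0.1. The 917 are fewer than the share of 0.05 of the 18625 probe sets that chance alone gives. After quantile normalization 21 passed, 9 higher and 12 lower, so the larger number of higher probe sets turned with the scaling. A second probe set of Fasn gave 0.58 (adjusted p = 0.999), and a second one of Spns2 gave −0.90 (adjusted p = 0.14). Cd36 had 381 ± 70 and 821 ± 105 (1.08, SE 0.21, adjusted p = 0.0997), Scd2 had 2030.3 ± 291 and 4030.5 ± 662 (0.98, adjusted p = 0.0592) and Scd had 139 ± 25.6 and 1309.6 ± 162 (3.10, adjusted p = 0.572). Ucp1 had 14.6 ± 15.8, at background, and 144 ± 71 (2.40, 3.76 with no offset and 1.36 with offset 64, adjusted p = 0.112). None of these 4 passed. For Scd the spread in the model is shared by all 4 groups, and the lean control signals varied far more than the obese ones. Its adjusted p is therefore not a measure of the spread within the obese groups.

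The count in obese rats moved with single arrays. Without obese rosiglitazone 1 the count was 0, without obese rosiglitazone 3 it was 1, without obese control 3 it was 2, without obese control 2 it was 3, without obese control 1 it was 4, without lean rosiglitazone 1 it was 8 and without lean rosiglitazone 2 it was 20. Over the alternatives the adjusted p ranged from 0.00371 to 0.106 for Fabp4, from 0.0113 to 0.17 for Rbp7, from 0.000125 to 0.0665 for Slc22a13, from 0.00456 to 0.237 for Fasn, from 0.00623 to 0.106 for Fabp5 and from 0.00623 to 0.109 for Spns2, and each of these upper ends came without obese rosiglitazone 1. That array is in the lower spike-in class, like all of its group. Within the lower class (2 control against 3 drug arrays) 18 probe sets were called, and with the class as a covariate 34, which held all 13.

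In obese rats 8 lists passed camera. The adipocyte markers had 1 of 14 that rose, Fabp4, and 0 that fell (3 and 0 adjusted over the list alone; median 0.27, adjusted p = 2.12e-07, and adjusted p = 0.215 with an estimated correlation). Adipoq had 500.4 ± 125 and 586 ± 51.9 (0.25, adjusted p = 0.999). Fatty acid synthesis had 1 of 19 that rose, Fasn, and 0 that fell (6 and 0 adjusted over the list alone; median 0.20, adjusted p = 4.56e-07, and adjusted p = 0.215 with an estimated correlation). PPARgamma targets had 1 of 29 that rose, Fabp4, and 0 that fell (4 and 0 adjusted over the list alone; median 0.23, adjusted p = 8e-06, and adjusted p = 0.278 with an estimated correlation). Endothelial markers were higher, with 0 of 13 past the test (2 and 0 adjusted over the list alone; median 0.33, and 0.18 within the lower spike-in class; adjusted p = 2.12e-06, and adjusted p = 0.38 with an estimated correlation). Tek, an angiopoietin receptor gene, had 1084 ± 295 on control diet and 1565 ± 135 on the drug (0.56, adjusted p = 0.523), and Emcn had 0.52. Proximal tubule markers were lower, with 0 of 29 past the test (1 and 6 adjusted over the list alone; median −0.10, adjusted p = 0.00464, and adjusted p = 0.533 with an estimated correlation), and the list did not pass with the spike-in class as a covariate (median −0.04). The sulphate transporter gene Slc13a1 had 929 ± 209 and 401 ± 126 (−1.21, adjusted p = 0.149). Cell cycle genes were lower, with 0 of 22 past the test (0 and 2 adjusted over the list alone; median −0.16, and −0.25 with the spike-in class as a covariate; adjusted p = 0.00204, and adjusted p = 0.533 with an estimated correlation). Kif11, a mitotic motor gene, had 935 ± 33.3 and 564 ± 103 (−0.73, adjusted p = 0.0997). Top2a, a topoisomerase gene, had 329.5 ± 21.3 and 142 ± 59 (−1.19, adjusted p = 0.276). A second probe set of Top2a gave −0.38 (adjusted p = 0.999), and a second one of Kif11 gave −0.96 (adjusted p = 0.987). Fatty acid oxidation was lower, with 0 of 28 past the test (0 and 0 adjusted over the list alone; median −0.09, adjusted p = 0.00919, and adjusted p = 0.533 with an estimated correlation). Inflammation and leukocytes was lower, with 0 of 27 past the test (0 and 0 adjusted over the list alone; median −0.20, adjusted p = 0.0337, and adjusted p = 0.606 with an estimated correlation).

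**Figure D2:**
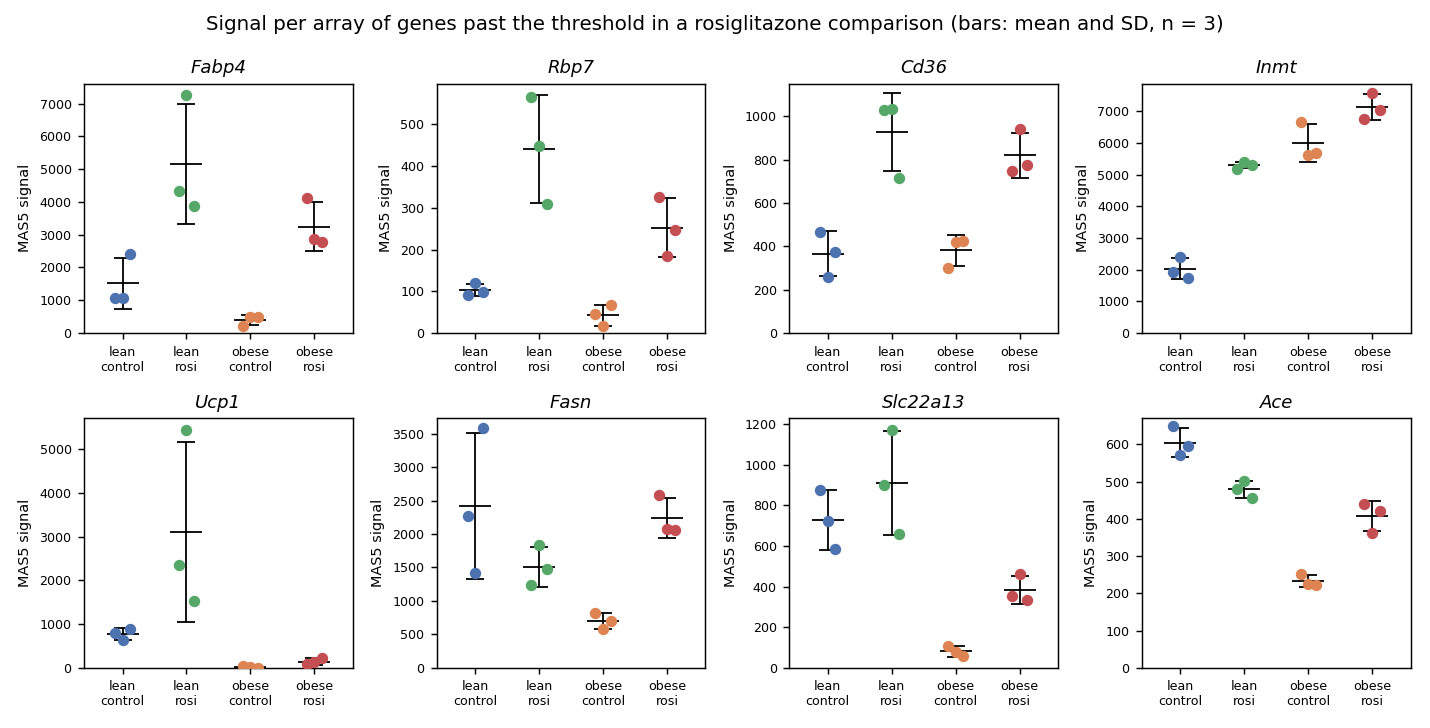
Signal on a linear scale from 0 for 8 genes in the 4 groups, with 1 point per array and bars for the mean ± SD (n = 3). Fabp4 had a mean of 403 in obese control and 3249.7 in obese rosiglitazone rats, and Inmt 2024 in lean control and 5300.5 in lean rosiglitazone rats.

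Rosiglitazone against control over both body types gives the drug effect averaged over both body types. Fabp4 (log2 change 2.42, SE 0.26, adjusted p = 0.00324), Rbp7 (2.08, SE 0.23, adjusted p = 0.00318), Cd36 (1.20, 2.3-fold, SE 0.15, adjusted p = 0.00518) and Inmt (0.82, SE 0.08, adjusted p = 0.00067) rose with the drug (n = 6 per side). Ucp1 (2.10, SE 0.32, adjusted p = 0.0456) and Scd2 (0.77, SE 0.12, adjusted p = 0.0448) rose as well, and Cotl1 fell by 0.51 (SE 0.08, adjusted p = 0.0456). From obese control signals at background, the changes with offset 64 were 1.57 for Rbp7 and 1.55 for Ucp1, and Ucp1 then did not pass (adjusted p = 0.0844, and 0.1 with no offset). Other probe sets of Scd2 (0.93 and 0.74) did not pass. In all 11 probe sets of 9 genes passed, 9 higher and 2 lower, and 7 of them were non-overlapping within both body types. The remaining genes, Slc22a13 and Tro, were chosen after their values were seen and rose by 1.19 (adjusted p = 0.0175) and 0.65 (adjusted p = 0.0456). Over all probe sets 0.6% were non-overlapping, where chance gives 0.5%, and 946 had an unadjusted p under 0.05. The 946 lie close to the share of 0.05 of the 18625 probe sets that chance alone gives.

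Over the alternatives the adjusted p stayed below 0.05 for Inmt (9.84e-05 to 0.00956), Fabp4 (0.000525 to 0.0289), Rbp7 (0.00136 to 0.0193) and Cd36 (0.00409 to 0.0304). It reached 0.183 for Ucp1 and Scd2 and 0.21 for Cotl1. The adjusted p of Ucp1, Scd2 and Cotl1 passed 0.05 without any of several single arrays, with 0.183 without obese control 3 for each. The count was 4 without lean control 2 or without obese rosiglitazone 1, 5 without obese control 3, 6 without lean rosiglitazone 1, obese control 2 or obese rosiglitazone 3, and 7 without obese rosiglitazone 2.

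Over both body types 5 lists passed. PPARgamma targets had 3 of 29 that rose, Fabp4, Ucp1 and Cd36, and 0 that fell (10 and 0 adjusted over the list alone; median 0.23, and 0.13 within the lower spike-in class; adjusted p = 5.43e-12, and adjusted p = 0.0607 with an estimated correlation). Adipocyte markers had 2 of 14 that rose, Fabp4 and Ucp1, and 0 that fell (8 and 0 adjusted over the list alone; median 0.44, and 0.21 within the lower class; adjusted p = 7.1e-16, and adjusted p = 0.0562 with an estimated correlation), while Adipoq had 0.39 (adjusted p = 0.662). Fatty acid synthesis had 1 of 19 that rose, Scd2, and 0 that fell (4 and 0 adjusted over the list alone; median 0.06, adjusted p = 0.00556, and adjusted p = 0.707 with an estimated correlation), and its median was −0.02 within the lower spike-in class. Endothelial markers were higher with 0 of 13 past the test (0 and 0 adjusted over the list alone; median 0.21, and 0.08 within the lower class; adjusted p = 0.00369). Fibrosis and extracellular matrix was lower with 0 of 25 past the test (0 and 2 adjusted over the list alone; median −0.15, adjusted p = 0.00262). Both had adjusted p = 0.707 with an estimated correlation. Pparg itself had a change of 0.32 (adjusted p = 0.993).

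The difference in the rosiglitazone effect between obese and lean rats asks whether body type changed the response. No probe set passed: limma gave 0 calls, with 802 at an unadjusted p under 0.05 and 1 at an adjusted p of 0.1. The 802 are fewer than the share of 0.05 of the 18625 probe sets that chance alone gives. The calls made in 1 body type alone are therefore not shown to differ from the other. The 10 probe sets of smallest p included that of Inmt (difference −1.14, SE 0.15, adjusted p = 0.0546), whose adjusted p ranged from 0.00559 to 0.301 over the alternatives, Nkd2 (2.19, adjusted p = 0.124), Ace (1.09, adjusted p = 0.173), Fasn (2.26, adjusted p = 0.235), Slc22a13 (1.77, adjusted p = 0.344), Ces1d (−1.32, adjusted p = 0.344) and Agt, angiotensinogen (−0.79, adjusted p = 0.398). Fabp4 had a difference of 1.22 (SE 0.52, adjusted p = 0.992). Without lean control 2 the count was 4. Lists that passed camera for this difference are given in the closing section. Across the 18625 probe sets, which are not independent replicates, the drug effects in lean and obese rats correlated with r = 0.0426, against −0.00093 in simulated unchanged groups, and with r = −0.0015 after the spike-in class was added as a covariate. No gene was called in both body types at 0.05 (0 shared, limma, 893 and 917 at an unadjusted p under 0.05). Only 1 probe set in lean and 13 in obese rats were called, where independence gives 0.000483 shared higher ones, so the 0 says little. Cd36 and Rbp7 were shared at an adjusted p of 0.1.

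Obese against lean on rosiglitazone asks which body type differences were seen in treated rats. Cox8b and Ucp1 were again lower in obese kidneys: Cox8b had 1429 ± 650.3 in lean and 57.2 ± 30.4 in obese rats (SD, n = 3 each; log2 change −4.30, SE 0.41, adjusted p = 9.74e-05; obese signal at background, −3.57 with offset 64), and Ucp1 had 3109 ± 2056 and 144 ± 71 (−4.19, SE 0.46, adjusted p = 0.000364). Car3 (−2.18, adjusted p = 0.00274) and Cidea (−2.02, adjusted p = 0.00209) were lower too. Fabp4, by contrast, had 5154 ± 1836 and 3249.7 ± 747 (−0.63, adjusted p = 0.378). Sgk1, a kinase that acts on sodium channels, had 3207 ± 619 in lean and 6642 ± 424 in obese rats (1.06, SE 0.14, adjusted p = 0.000833), and the matrix protein gene Matn1 had 651 ± 238 and 2672 ± 214 (2.07, SE 0.21, adjusted p = 0.000118).

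In all 932 probe sets of 701 genes differed on the drug, 448 higher and 484 lower, all of them non-overlapping, and 154 by at least 2-fold. Unadjusted p was under 0.05 for 3677. Over all probe sets 23.3% were non-overlapping, where chance gives 10%. The share of higher probe sets was 48.1%, and 33.6% (269 of 800) with each array centred on its median. The other higher genes named by the rule were Wtap (2.70), RT1-Db1 (2.61), Nt5dc1 (2.26), Fubp3 (2.21), Cd44 (2.08, lean signal at background, 1.55 with offset 64), Zeb2 (2.01) and Plcb3 (1.96). The other lower ones were RT1-CE16 (−3.23), RT1-Ba (−3.02), Poteml2 (−2.27) and Pik3r1, a subunit of the kinase that insulin signals act on (−2.02). A dimmer probe set of Gtpbp4, chosen after its values were seen, had −3.04 (adjusted p = 4.47e-06), and its brighter one had −1.96. Other probe sets of Wtap (0.24), RT1-Db1 (0.69), Nt5dc1 (0.39), Fubp3 (−0.33), Cd44 (0.46) and RT1-Ba (0.28) did not pass, and neither did 4 other probe sets of Zeb2.

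On the drug, Hbb differed by 1.55 (adjusted p = 0.0163), Alas2 by 1.20 (adjusted p = 0.0194) and Hba-a3 by 1.64 (adjusted p = 0.00344). Slc4a1, another gene of the red blood cell list, had −0.13 (adjusted p = 0.632). That list was too short to be tested. Cd74 was lower (−0.53, adjusted p = 0.00877), and Spp1 (0.63, adjusted p = 0.0841) and Havcr1 (1.96, adjusted p = 0.137) did not pass. On the drug, 2 of 3 lean arrays and 0 of 3 obese arrays were in the higher spike-in class. Within the lower class (1 lean against 3 obese, with the lone array assumed to vary like the others) 533 probe sets were called, and with the class as a covariate 692, of which 526 were among the 932. The count was 474 without obese rosiglitazone 2, 486 without obese rosiglitazone 1, 518 without obese rosiglitazone 3 and 531 without lean rosiglitazone 1. Hbb (up to 0.0715 without obese rosiglitazone 1), Alas2 (up to 0.0814 without the same array), Plcb3 (up to 0.116) and Zeb2 (up to 0.135) did not pass without either lean rosiglitazone 3 or obese rosiglitazone 2, and neither did Cd44 (0.0552 and 0.069) or RT1-Ba (0.0607 and 0.0715).

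The body type differences on the separate diets, which share no array, correlated across probe sets with r = 0.615 (simulated unchanged groups −0.00055). The slope of the difference on the drug against that on control diet was 0.614, and 0.939 after correction for noise, with a range from 0.81 to 1.09 without single arrays and a jackknife SE of 0.24. The simulated arrays varied independently, so no correlation could arise there, and they say nothing of a technical difference common to both diets. On both diets more lean than obese arrays were in the higher spike-in class, which by itself can raise the correlation, the slope and the number of shared calls. Of the 882 probe sets called on control diet, 852 had the same direction on the drug and 435 were called again in it, 179 higher and 256 lower, where independence gives 9.65 and 12.5. Their median absolute log2 change was 0.64 on control diet, and their median change in that direction was 0.47 on the drug. Selection on the first comparison gives such a drop by itself. Whether the drug moved genes back towards lean levels was asked with the correlation between the body type difference on control diet and the drug effect in obese rats. It was r = −0.374, while unchanged groups that share the obese control arrays gave −0.501 in simulation. The simulated groups held no body type difference, unlike the rats, and a real difference by itself weakens such a negative r. The observed and simulated r are therefore not on the same footing and do not decide the question. The covariance was −0.026 against −0.0226, slightly further in the negative direction, but no spread is given for the simulated value. Of the 13 probe sets called for the drug in obese rats, 11 were called in the opposite direction between obese and lean rats on control diet. Ace, Fabp4, Fabp5, Fasn, Nkd2, Slc22a13, Slc7a12 and Tro were lower in obese rats and higher with the drug (8 probe sets, 0.232 by independence), and Cotl1, Spns2 and 1 unnamed probe set were the reverse (3 probe sets, 0.0861 by independence). These comparisons share the obese control arrays, which by itself gives opposite directions.

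**Figure D3:**
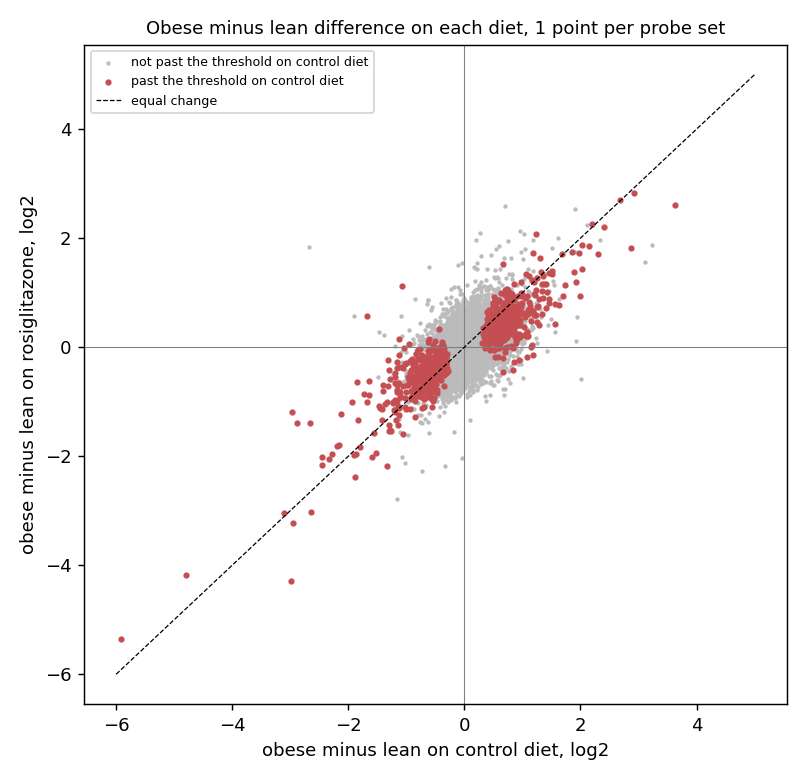
Log2 difference of obese minus lean rats on control diet (x axis) and on rosiglitazone (y axis), 1 point per probe set (18625), with the 882 probe sets called on control diet in red and a dashed line where both are equal. Of the 882, 852 had the same direction on both diets.

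Obese against lean over both diets gives the body type difference averaged over both diets. Obese kidneys had more Ccn1 (log2 change 1.73, SE 0.16, adjusted p = 1.57e-05; n = 6 per side), Havcr1 (2.15, SE 0.50, adjusted p = 0.0124) and Spp1 (0.79, adjusted p = 0.00216). Havcr1 passed on neither diet alone (adjusted p = 0.0831 and 0.137), and Spp1 did not pass on the drug. Adh1c, an alcohol dehydrogenase gene, had 574 ± 170.1 and 694 ± 98.1 in the lean groups and 1815 ± 133 and 2306 ± 343 in the obese groups (1.69, SE 0.13, adjusted p = 3.61e-06). Ucp1 (−4.49, SE 0.32, adjusted p = 3.61e-06; −3.61 with offset 64) and Slc22a7 (−1.29, adjusted p = 2.77e-06) were lower. In all 2665 probe sets of 1923 genes differed, 1432 higher and 1233 lower in obese rats, 172 by at least 2-fold, and 1603 of them were non-overlapping within both diets. Over all probe sets 9.9% were non-overlapping, where chance gives 0.5%, and 5229 had an unadjusted p under 0.05. The share of higher probe sets was 53.7%, but 37.7% (949 of 2518) with each array centred on its median, so the majority turned with the scaling. The other higher genes named by the rule were Wtap (2.69), RT1-Bb (2.34), Ubd (2.01), Lypd2 (1.85) and Zeb2 (1.81, with 4 other probe sets that did not pass). The other lower ones were Cox8b (−3.64, and −2.85 with offset 64), RT1-CE16 (−3.09), RT1-Ba (−2.84, with another probe set at 0.68), Gtpbp4 (−2.12), Slc22a13 (−2.08), Thrsp (−2.03) and AKR1C3l1 (−1.94). Dimmer probe sets again lay further out, chosen after their values were seen: RT1-Db1 had 3.12 (adjusted p = 1.27e-07, 2.53 with offset 64, and 0.89 for its brighter one), Fubp3 2.31 (and −0.40), Nt5dc1 2.23, Cav2 1.95, Gtpbp4 −3.07 (adjusted p = 6.18e-08), Pxmp4 −2.24 and Thrsp −2.13.

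Over both diets 15 lists passed camera. Adipocyte markers had 0 of 14 that rose and 9 that fell (0 and 12 adjusted over the list alone; median −0.88, adjusted p = 3.81e-09, and adjusted p = 0.129 with an estimated correlation), among them Cfd (−1.91), Cidea (−1.55), Fabp4 (−1.24) and Adipoq (−0.51). PPARgamma targets had 5 of 29 that rose and 10 that fell (5 and 12 adjusted over the list alone; median −0.24, and −0.16 within the lower spike-in class; adjusted p = 0.000596), and fatty acid synthesis had 0 of 19 and 6 (1 and 10 adjusted over the list alone; median −0.30, adjusted p = 0.000197), both with adjusted p = 0.302 with an estimated correlation. Lpl rose by 0.74 and Angptl4, which inhibits it, by 0.74. Fatty acid oxidation had 0 of 28 that rose and 8 that fell (1 and 9 adjusted over the list alone; median −0.18, adjusted p = 0.000585, and adjusted p = 0.333 with an estimated correlation), with Acadm at −0.43 (SE 0.07, adjusted p = 0.000944) and Ehhadh at −0.48. Cholesterol synthesis had 0 of 20 and 3 (0 and 4 adjusted over the list alone; median −0.12, adjusted p = 0.0234, and adjusted p = 0.47 with an estimated correlation), with Insig1 at −0.49 and Lss at −0.53. Oxidative phosphorylation had 0 of 44 and 9 (0 and 13 adjusted over the list alone; median −0.14, and 0.004 after quantile normalization; adjusted p = 1.07e-05, and adjusted p = 0.484 with an estimated correlation). Ndufb3 fell by 0.33.

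Distal sodium and water transport had 13 of 24 members that rose and 1 that fell over both diets (16 and 2 adjusted over the list alone; median 0.40, adjusted p = 0.000146, and adjusted p = 0.0722 with an estimated correlation). Sgk1 rose by 0.73 (SE 0.10, adjusted p = 0.000324), Aqp3, a water channel of the collecting duct, by 0.71 (SE 0.13, adjusted p = 0.00213) and Nr3c2 by 0.46 (adjusted p = 0.00158). Proximal tubule markers had 2 of 29 that rose and 16 that fell (3 and 17 adjusted over the list alone; median −0.37, −0.15 after quantile normalization and −0.22 within the lower spike-in class; adjusted p = 1.78e-06, and adjusted p = 0.302 with an estimated correlation), with Anpep at −0.70 and Slc13a3 at −0.89. The renin angiotensin list had 0 of 9 that rose and 4 that fell (1 and 5 adjusted over the list alone; median −0.33, −0.20 after quantile normalization and −0.08 within the lower spike-in class; adjusted p = 0.00365, and adjusted p = 0.302 with an estimated correlation), with Ace at −0.77 (adjusted p = 9.31e-05) and Agt at −0.55 (adjusted p = 0.000493). The thick ascending limb and medulla list did not pass (adjusted p = 0.486), with 5 of its members risen and 2 fallen (6 and 3 adjusted over the list alone). Clu, the clusterin gene, rose by 1.26 and Slc14a2, a urea transporter gene, by 0.61 (3 other probe sets at 0.34, 0.07 and 0.19 did not pass), while Aqp1, the water channel of the proximal tubule and thin limb, fell by 0.45.

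Fibrosis and extracellular matrix had 10 of 25 members that rose and 0 that fell over both diets (13 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.000107, and adjusted p = 0.304 with an estimated correlation), with Timp1, an inhibitor of matrix proteases, at 1.23 (SE 0.28, adjusted p = 0.0111) and Ccn2 at 0.42. Tubular injury had 9 of 22 that rose and 2 that fell, Krt19 and Tff3 (10 and 2 adjusted over the list alone; median 0.32, adjusted p = 0.00521, and adjusted p = 0.302 with an estimated correlation), with Cp, the ceruloplasmin gene, at 0.72 (another probe set at 0.30 did not pass). Smooth muscle markers had 2 of 9 that rose, Acta2 (0.41) and Myl9 (0.29), and 0 that fell (5 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.0425, and adjusted p = 0.42 with an estimated correlation). Oxidative stress and glutathione had 4 of 29 that rose and 7 that fell (4 and 9 adjusted over the list alone; median −0.14, and −0.06 after quantile normalization; adjusted p = 0.0484, and adjusted p = 0.554 with an estimated correlation), with Gstm2 and Ucp2 risen by 0.71 and 0.56 and Cyba fallen by 0.65. The unfolded protein response had 1 of 21 that rose and 5 that fell (1 and 7 adjusted over the list alone; median −0.15, and −0.06 after quantile normalization; adjusted p = 0.0206, and adjusted p = 0.514 with an estimated correlation), with Calr at −0.32. Xenobiotic metabolism had 2 of 18 that rose and 5 that fell (2 and 6 adjusted over the list alone; median −0.18, adjusted p = 0.0398, and adjusted p = 0.42 with an estimated correlation). Inflammation and leukocytes did not pass (adjusted p = 0.0501), with 7 members risen and 1, Cd74, fallen (8 and 1 adjusted over the list alone), and Icam1, an adhesion molecule gene, rose by 1.32 (SE 0.23, adjusted p = 0.0024). Glucose metabolism and insulin signalling did not pass (adjusted p = 0.958), with 4 members risen and 2 fallen (5 and 2 adjusted over the list alone), Pik3r1 at −1.81 and Irs2 at −0.76.

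The remaining lists had an adjusted p of 0.0551 for endothelium, 0.0664 for immediate early genes, 0.1 for podocytes, 0.23 for intercalated cells, 0.403 for lymphocytes and for cell cycle, 0.462 for eicosanoids, 0.529 for the circadian clock and 0.958 for urothelium. With the spike-in class as a covariate 2000 probe sets were called over both diets, of which 1677 were among the 2665, and within the lower class 1147. The lists of smooth muscle, oxidative stress, xenobiotic metabolism and the unfolded protein response did not pass with that covariate. Neither did Acta2, whose adjusted p reached 0.0555 over the alternatives, Adipoq, which reached 0.0557, Irs2, which reached 0.0863, or Myl9, which reached 0.177. Angptl4 (0.0819 without obese control 3) and Lss (0.106 without lean rosiglitazone 2) did not pass without most of the single arrays, and Havcr1 stayed below 0.05 with at most 0.0404. Leaving out single arrays kept the count between 1919 and 2705.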

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

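The tests of other splits of the samples were chosen before the results were seen, and the tests of spike-in class, fat tissue, sequence differences and leukocytes only afterwards. No probe set differed in its rosiglitazone effect between obese and lean rats (0 in limma, and 802 at an unadjusted p under 0.05, fewer than chance alone gives). Still, 5 of 27 lists passed camera for that difference and are given for that reason. Fatty acid synthesis genes had a higher drug effect in obese rats (median difference 0.31, and 0.63 within the lower spike-in class; adjusted p = 3.93e-05, and adjusted p = 0.675 with an estimated correlation), with 0 of 19 members past the test and 2 adjusted over the list alone. Endothelial markers had a median difference of 0.36 (adjusted p = 0.000457, and adjusted p = 0.925 with an estimated correlation). Fatty acid oxidation was lower by a median difference of −0.16 (adjusted p = 0.000302, and adjusted p = 0.925 with an estimated correlation). Cell cycle genes had −0.25 (adjusted p = 0.0104, and adjusted p = 0.925 with an estimated correlation). Proximal tubule markers had −0.20 (−0.12 after quantile normalization and −0.08 within the lower spike-in class; adjusted p = 0.0382, and adjusted p = 0.925 with an estimated correlation), and did not pass with the spike-in class as a covariate. In these last 4 lists 0 members passed over all genes and 0 adjusted over the list alone, of 13, 28, 22 and 29 measured. Of 100 splits 63 brought as many lists past camera (real 5, highest other 15), so chance could not be excluded for the number of lists.

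Over both diets 1 of 100 splits of the samples, the real one, called as many probe sets between obese and lean rats (2665, highest other 322). This makes chance an unlikely cause of the number of probe sets. For the lists 4 of 100 splits brought as many past camera (15, highest other 16). That share is under 0.05, but other splits brought as many or more lists past, so chance is not excluded for them. For rosiglitazone over both body types 2 of 100 splits called as many probe sets (11, highest other 14). That share is under 0.05, but another split called more than the real one, so chance is unlikely but not excluded. As many lists were brought past by 59 of 100 (5, highest other 12), so chance could not be excluded for the lists either. For the difference between body types the real count was 0, which all 100 of 100 splits reach whatever they call (highest other 14), so the count of splits says nothing about chance. The correlation of the drug effects in lean and obese rats was reached by 34 of 100 splits (0.0426, highest other 0.232), so chance could not be excluded for it.

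Groups of 3 against 3 make 10 splits, too few for a share under 0.05. For obese against lean on control diet 1 of 10 splits, the real one, called as many probe sets (882, highest other 1) and 1 of 10 brought as many lists past (12, highest other 11). On rosiglitazone 1 of 10 called as many (932, highest other 0). For rosiglitazone in lean rats 5 of 10 called as many probe sets (1, highest other 4) and 8 of 10 as many lists (4, highest other 12), and in obese rats 1 of 10 (13, highest other 0) and 3 of 10 (8, highest other 11). For the correlation of the body type difference with the drug effect in obese rats, 4 of 20 assignments of the obese rats lay as far below 0 (real −0.374, −0.43 among the others), and 20 are too few for a share under 0.05.

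The first pattern is the number of body type calls, since 4 of 6 lean arrays and 1 of 6 obese arrays were in the higher spike-in class. With the class as a covariate 995 probe sets were called on control diet, 793 of them among the 882, and 2000 over both diets, 1677 of them among the 2665, which argues against hybridization class as the whole cause. The body type difference within the higher class and within the lower class, which share no array, correlated across probe sets with r = 0.469. The class was defined from these arrays, and part of the difference may still come from it, since the 4 lists of smooth muscle, oxidative stress, xenobiotic metabolism and the unfolded protein response did not pass over both diets with the covariate. The leptin receptor mutation and obesity itself stay open as untested biological causes, and so does the amount of fat left on the kidneys for the lower adipocyte markers.

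The second pattern is the change of fat cell genes with rosiglitazone. In obese rats the 13 adipocyte markers other than Fabp4 had a median change of 0.24 (SD 0.71, from −0.05 to 2.4). The 7 with a lower signal than Fabp4 in obese control rats had one of 0.45 (SD 0.90), and Fabp4 had 3.03. The 2.4 was that of Ucp1 from a signal at background, and was 3.76 with no offset and 1.36 with offset 64. Fabp4 was singled out for its high change among the genes called, which by itself favours a gap. The values therefore do not decide whether more fat tissue in the samples was the whole cause of the Fabp4 rise. Fat tissue as all or a part of it and a direct effect of the drug on kidney or vessel cells stay open. Ucp1, Cidea, Cox8b, Car3 and Plin1, chosen after their means were seen to be higher in lean rats on the drug, had a median correlation of residuals of 0.63 between rats of the same group. This lay above 99.98% of 10000 random sets of 5 genes (median −0.011, 95th percentile 0.27), but above 92.2% of 10000 sets of 5 genes from 1 of 25 other fixed lists each (median 0.23, 95th percentile 0.71), so shared regulation could give it as well as an amount of fat tissue that differs between samples, and both stay open.

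The third pattern is the RT1 genes of the major histocompatibility complex, of which 13 of 23 probe sets (56.5%) were called over both diets, against 14.3% of the others. Of these, 7 were higher and 6 lower in obese rats. The 7 higher ones had a median of 0.89, while the 24 genes of the inflammation and leukocyte list other than RT1 had one of 0.22 (SD 0.37, highest 1.32). The 7 were taken because they were called higher, which by itself raises their median, while the list was not selected. This comparison therefore cannot decide on more leukocytes in obese kidneys, which stay open as a cause. Cd74 fell by 0.37 (limma, adjusted p = 0.00366). Probe sets of the same RT1 gene differed in their change by a mean SD of 0.99 over 4 genes, against 0.17 in random genes (permutation p = 1e-04, one-sided, the smallest that 10000 draws can give). The probe sets of RT1-S3, 1 of the 4, lay close together (−0.66 to −0.50). RT1 was tested after its changes were seen, and the random genes were matched in number of probe sets but not in size of change. A wider spread was therefore likely beforehand, and the p does not decide on a cause. Such a spread can come from sequence differences between the animals or from probe sets that read several RT1 genes. These 2 were not told apart.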

How the results depend on the processing

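The alternatives that use the spike-in class were chosen after the array summaries were seen. Of 158 alternatives for counts, lists and correlations other than leaving out arrays, 107 stayed within 1.5 times the value or within its spread and 51 moved further. A reversal could be marked only for the corrected slope and the correlation of body type difference and drug effect, not for counts, and 0 were marked. The correlation of the drug effects, 0.0426, was below its SE of 0.14 and so could not be marked. It went to −0.0015 with the class. The majority of higher probe sets turned over both diets (53.7% to 37.7% with median centring) and in obese rats (69.2% to 42.9% with quantile normalization), and so did the oxidative phosphorylation median between body types with quantile normalization. Of 9942 alternatives for named genes 9307 kept their side of the threshold, 502 lost a call and 133 gained one. Direction was checked only where the gene was called in the main or the alternative fit, and there 0 reversed. Of 179 named gene calls 116 held under every alternative chosen beforehand. Nothing in the labels says that a replicate number marks a shared batch, and 4 of 18 same-numbered pairs had residual correlations over 0.1 (−0.179 to 0.182, median 0.07, against −0.0235 for other pairs), so the block is given here alone. Between the lean groups each array correlated best with its own number (0.1, 0.132 and 0.182), a hint from the data that leaves pairing there open. Where a count moved, the cause was not tested, except that a looser threshold calls more and fewer arrays give less precision. Dim probe sets limit the results, since those under the filter were not tested.

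For obese against lean on control diet the count was 548 with eBayes without trend and robust, 1384 with array weights, 1470 at an adjusted p under 0.1, 164 within the lower class and 52 within the higher, and 325 to 1003 without single arrays. On rosiglitazone it was 589, 1631 at 0.1, 533 within the lower class, and 474 to 1033 without single arrays. Over both diets it was 1147 within the lower class and 1919 to 2705 without single arrays.

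For rosiglitazone in lean rats the count was 2 with the 60th percentile filter, quantile normalization, median centring, array weights or the replicate block, 10 at an adjusted p under 0.1, 4 with the class as a covariate or without both lean arrays of the lower class, 23 within the lower class, 0 within the higher class (limma, 713 unadjusted), and 1 to 4 without single arrays. In obese rats it was 7 with no filter, 21 with quantile normalization, 2 with eBayes without trend and robust, 31 with only the groups compared, 36 with array weights, 26 at 0.1, 34 with the class, and 0 to 20 without single arrays. Over both body types it was 5 with no offset, 7 with offset 64 or no filter, 4 with eBayes without trend and robust, 6 with the replicate block, 20 with the class, and 4 to 11 without single arrays. For the difference between body types it was 1 with the 60th percentile filter, quantile normalization, array weights or a threshold of 0.1, 3 with the class, and 0 to 4 without single arrays.

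With an estimated correlation camera brought 0 lists past in each of the 6 comparisons tested, where the lowest adjusted p was 0.0562. With fry 5 passed on control diet, 0 in lean rats, 0 in obese rats, 10 over both diets, 2 over both body types and 0 for the difference. For the difference 3 lists passed with quantile normalization and 3 with the mean over probe sets, and over both body types 9 passed with the class. Without single arrays 10 to 17 lists passed on control diet, 3 to 6 in lean and 4 to 11 in obese rats, 11 to 19 over both diets, 4 to 10 over both body types and 3 to 6 for the difference. The correlation of body type difference and drug effect ranged from −0.472 to −0.286 without single arrays (jackknife SE 0.14), the corrected slope from 0.81 to 1.09 (0.24), and the correlation of the drug effects from −0.0365 to 0.128 (0.14).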

Other observations

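The test of genes next to Lepr and the alternatives with the spike-in class were chosen after the results were seen. Of the red blood cell genes, too few to be tested as a list, 3 were higher in obese rats over both diets: Hba-a3 by 1.16 (SE 0.18, adjusted p = 0.00117), Alas2, the heme synthesis enzyme of red cells, by 0.75 (adjusted p = 0.0166) and Hbb by 0.75 (adjusted p = 0.0443). On rosiglitazone Hba-a3 differed by 1.64 (adjusted p = 0.00344), Alas2 by 1.20 (adjusted p = 0.0194) and Hbb by 1.55 (adjusted p = 0.0163). On control diet none of the 3 passed: Hba-a3 had 0.68 (adjusted p = 0.166), Alas2 0.295 (adjusted p = 0.603) and Hbb −0.047 (adjusted p = 0.96). The averages of Alas2 and Hbb thus came mainly from the rats on the drug. Slc4a1, also an intercalated cell gene, had −0.16 over both diets (adjusted p = 0.27). Hbb did not pass without 9 of the 12 arrays in turn, with an adjusted p of up to 0.114 without obese control 2. The 4 measured adrenal cortex markers had no call on control diet: Cyp11a1 had 0.33 (adjusted p = 0.651), Cyp21a1 0.21, Nr5a1 0.09 and Scarb1 −0.02.

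Single genes of the xenobiotic and eicosanoid lists differed between body types over both diets. Slco1a1, an organic anion transporter gene, went from 5522 ± 625 in lean control to 2124 ± 104 in obese control rats and fell by 1.21 over both diets (SE 0.12, adjusted p = 3.97e-05), while Sult1a1, a sulphotransferase gene, rose by 0.93 (SE 0.12, adjusted p = 0.000312). Of the 19 eicosanoid genes measured, 2 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.462). Ptgs2, which encodes cyclooxygenase 2, rose by 1.19 (SE 0.26, adjusted p = 0.00731), and Cyp4f6 (−0.49, SE 0.08, adjusted p = 0.000992) and Cyp4a3 (−0.37, adjusted p = 0.00227) fell.

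Egr1, Slc5a2, Irf7 and Isg15 had other signals in arrays 3 of both lean groups than in the other lean arrays. Egr1 had 3333, 7768.5, 7495 and 5523 in arrays 1 and 2 of the lean groups, 1393 and 1725 in arrays 3, and 710.3 to 2067 in the obese arrays. Slc5a2 had 36.5 to 57.6, at background, in arrays 1 and 2 of the lean groups, 502 and 667 in arrays 3, and 165 to 1704 in the obese arrays. Irf7, an interferon response gene, had 2093 and 2262 in arrays 3, 401.5 to 533 in the other lean arrays and 455 to 1308 in the obese arrays, and Isg15 had 805 and 539, 145 to 219, and 285 to 402. Irf7, Isg15 and this grouping of single genes were chosen after their values were seen. Over both diets 0 of 19 immediate early genes rose and 4 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.0664): Egr1 (−1.57, SE 0.43, adjusted p = 0.0327), Junb (1504 ± 675 and 1864 ± 1251 in the lean groups, 874 ± 177 and 643 ± 52.7 in the obese groups, SD, n = 3 each, adjusted p = 0.027), Ier2 (−0.91, adjusted p = 0.0354) and Zfp36 (−0.85, adjusted p = 0.0146). With the spike-in class as a covariate none of these 4 passed. Egr1 then had −0.86, with an adjusted p from 0.000543 to 0.0866 over its alternatives, and Slc5a2 went from 2.56 (SE 0.74, adjusted p = 0.0414) to 1.35, with 0.000869 to 0.106.

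Whether the mutated Lepr region carries other differences, such as linked variants, was tested as a hypothesis with the 60 genes next to Lepr in gene order, 30 on each side. Of these, 23 were measured and 4 were called between obese and lean rats, 17.4% against 16.3% of the other 10500 genes (Fisher's exact test, two-sided p = 0.782). No clustering of calls around Lepr was seen, though 23 genes could hide a small one.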
